A study of Mus musculus with 6 samples.

How the data were processed

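RNA was sequenced from cultured mouse bone marrow stromal/stem cells of 2 genotypes, WT and Nrf2 knockout, with 3 libraries each. Nrf2 is the common name of the transcription factor encoded by Nfe2l2, which switches on genes for antioxidant and detoxifying enzymes. The cells grew in DMEM with 10% serum, and the libraries were made from total RNA with an mRNA library kit, per the labels' protocols. The labels number the libraries 1 to 3 in each genotype without saying whether a number marks an animal, a culture or a day. The table's knockout columns also share a middle 1 that the WT columns lack, and its meaning is not given in the sources used here, so the knockout libraries may be repeats of 1 source. The p-values therefore measure the spread between these libraries, which may be partly technical.

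The deposited table lists 55401 mouse genes with raw read counts per gene and library. The submitters' processing notes name HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 and the build mm10, without saying which tool made which column. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart in these counts. The table also holds the authors' FPKM values. Each deposited FPKM equals the count divided by the table's exonic length and by the column total, within 0.005. Of the gene IDs, 99.5% were found in GENCODE release M21, and 99.4% of those had the same start and end, so coordinates are given as in the table, on mm10. The 217 rows whose symbol occurs more than once were resolved for gene lists to the row with the highest mean count. How reads that match near-identical gene copies were counted is not given in the sources used here, so members of such families (glutathione S-transferases Gstm and Gstp, Hspa1a and Hspa1b, ferritins) are uncertain.

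Column totals ran from 18381114 to 21323839 counts, so 3 counts correspond to 0.141 to 0.163 CPM (a count as a share of its library's total, times 1e+06). Intervals on count ratios are exact 95% intervals and cover counting error only. Replicates of a genotype differed by more than sampling noise, with a chi-square per degree of freedom from 3.24 to 161.57 over genes with at least 20 counts in a pair, where sampling alone gives 1.

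The gene lists, the rule for named genes and the test were set before the data were examined. The planned test depended on the table's unit: limma on log2(FPKM + 1) if the table held FPKM alone, and edgeR's quasi-likelihood test if it held raw counts. The table held both, so edgeR was the main test. It ran in R 4.3.3 with edgeR 4.0.16, filterByExpr (minimum count 10), TMM factors, genotype as the only term and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. All log2 fold changes are knockout over WT. A standard error is the absolute log2 fold change over the square root of the F statistic. CPM values are scaled with the TMM factors and given as mean ± SD over 3 libraries.

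The 40 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. Biological process terms given in the deposited table, with 10 to 500 genes, were tested by a one-sided Fisher exact test among higher and lower calls against the 9742 tested genes that carry a term. The genes named are Nfe2l2, Keap1, the 10 called genes with the largest log2 fold change in each direction, and up to 4 tested members with the smallest p in each list. Those 10 needed a mean FPKM of at least 5 in the higher genotype, no overlap between genotypes and a protein-coding type with a symbol that is not a predicted name, and some of them are not reported here. Lyz2 was named for its level, and Ephx1, Chac1, Ccl6, Ccl9 and Adamts12 were chosen after their values were seen.

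Alternatives covered the pseudocount, filters on low values, quantile, median and TMM scaling of FPKM, limma variants, DESeq2 1.42.0, a stricter threshold, the replicate number as a replicate block, and leaving out each library. Added after the data were seen were relative log expression, library total and upper quartile scaling, scaling to the macrophage list, a covariate for matrix RNA (the summed collagen and crosslinking list) and a robust fit. Relative to its highest library, that covariate was 0.265 to 1 in WT and 0.014 to 0.016 in knockout. It separates the genotypes, so a fit with it extrapolates from the 3 WT libraries. With it 18 of 19 collagen and crosslinking genes were still lower (median log2 fold change -4.48), so it does not remove matrix content. The scripts were tested on simulated counts for Nrf2 knockout against WT, over 13053 genes, with 200 genes drawn as changed and the proliferation list raised 2-fold. There edgeR recovered 11.9% of genes changed by 1.5-fold, 62.7% of those changed by 2-fold and 83.3% of those changed by 4-fold, and 6.5% of its calls fell on unchanged genes. The same share was 7.1% for limma and 23.4% for DESeq2. The simulation gave both genotypes the same spread per gene, while the measured coefficient of variation was 25.2% in WT and 6.5% in knockout. It also changed far fewer genes than the 32.9% called in the data, so these rates may not carry over.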

Results

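Messenger RNA was measured in cultured mouse bone marrow stromal/stem cells, WT and Nrf2 knockout, with 3 libraries of each genotype. The libraries held 19163730, 18381114 and 21323839 counts for WT, and 20544347, 21235480 and 20069243 counts for Nrf2 knockout. The labels do not say whether the 3 libraries of a genotype come from different animals, or whether the knockout libraries are repeats of 1 source, so each p measures the spread between these libraries, which may be partly technical. The series asks how loss of Nrf2 changes gene expression in these cells.

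Nfe2l2, the gene that encodes NRF2, lies on chromosome 2 from 75675513 to 75704641 on the minus strand (mm10; ENSMUSG00000015839). It had 3591, 3082 and 3628 counts in WT libraries and 118, 149 and 118 in knockout libraries. Its deposited FPKM was 46.1 ± 2.83 (SD, n = 3) in WT and 1.64 ± 0.19 (SD, n = 3) in knockout. After TMM scaling its knockout CPM was 3.66% of the WT CPM. The log2 fold change was -4.77 (SE 0.14; edgeR adjusted p = 2.2e-05). An exact permutation test of the 3 against 3 libraries gave p = 0.1, two-sided, the smallest that this design allows. The genotype labels thus match the measured Nfe2l2 level in 6 of 6 libraries. Keap1, whose protein holds NRF2 in check, had 72.0 ± 4.38 CPM in WT and 69.4 ± 0.28 CPM in knockout, with an edgeR adjusted p of 0.60.

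Knockout libraries had lower transcripts for NRF2-dependent enzymes of glutathione and detoxification and, by much larger factors, for collagens, contractile proteins and other stromal genes. Transcripts for chemokines, cell division and interferon response were higher. Macrophage transcripts were abundant in all 6 libraries: lysozyme 2 (Lyz2) stood at 15330 ± 1356 CPM in WT and 12420 ± 729 CPM in knockout. In total 4333 of 13184 tested genes (32.9%) passed an edgeR adjusted p of 0.05, with 1865 higher and 2468 lower in knockout. Changes of at least 2-fold numbered 514 higher and 1549 lower, and 890 genes were lower by at least 8-fold, against 34 higher. The 2 genotypes did not overlap for 50.9% of tested genes, where chance gives 10%.

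The count of changed genes was 6901 without WT replicate 1 and 2687 without WT replicate 2. It was 3654 without WT replicate 3, and 2491, 2748 and 2574 without knockout replicates 1, 2 and 3. The count thus depends on which WT libraries are kept, while leaving out any 1 knockout library gave like, lower counts. Within edgeR the split between directions was 1817 higher and 2495 lower with relative log expression factors, 1691 and 2405 with library totals, and 1732 and 2478 with upper quartile factors. With limma on log2(FPKM + 1), which tested 10696 genes, it was 1617 higher and 1431 lower, and in limma it was 1991 and 1374 after quantile normalization and 1973 and 1322 after median centring. With edgeR and libraries scaled to the macrophage list it was 303 higher and 3533 lower, and the median of all tested genes moved to -0.515.

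**Figure D1:**
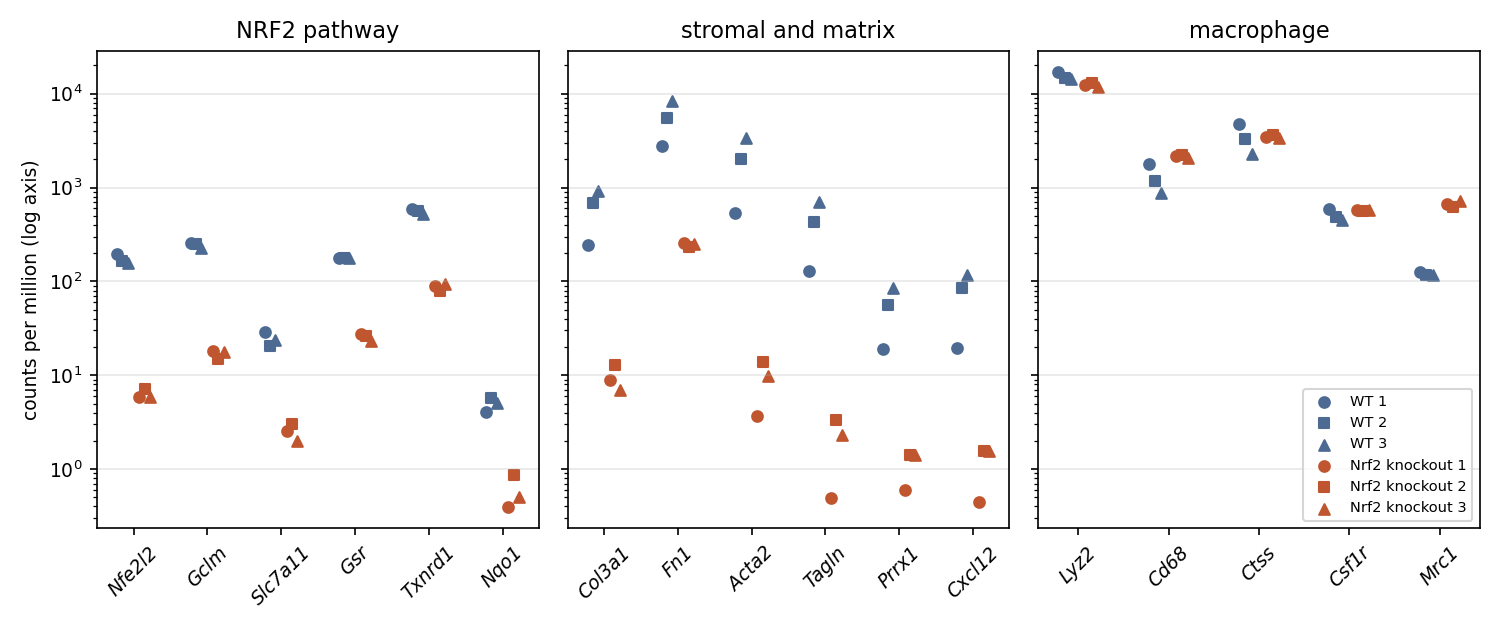
CPM (log axis) of 17 genes in each of the 6 libraries, with a point per library, in panels for NRF2 pathway, stromal and macrophage genes. Gclm sits near 245 CPM in WT and near 16.9 CPM in knockout, while the stromal genes differ several-fold among WT libraries and Lyz2 is high throughout.

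The NRF2 target genes fell in knockout as a group. In the glutathione and thioredoxin list 11 of 13 tested members fell and 0 rose (11 adjusted over the list alone), with a median log2 fold change of -1.85. Gclm, a subunit of the enzyme that starts glutathione synthesis, fell from 245 ± 15.2 to 16.9 ± 1.71 CPM. Gsr, glutathione reductase, fell 6.91-fold, and Txnrd1, thioredoxin reductase, fell 6.37-fold (edgeR adjusted p = 2.3e-05 and 4.0e-05). Camera gave an adjusted p of 7.1e-08, and an adjusted p = 0.10 with an estimated correlation.

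In the detoxification and conjugation list 16 of 21 tested members fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.40. Gsta3, a glutathione S-transferase, had 2804 counts over the WT libraries and 5 over the knockout libraries, and Mgst1, a microsomal transferase, fell 4.44-fold. Gstm2 and Gstp1 fell 6.07-fold and 4.53-fold, values that reads shared with close paralogs make uncertain. The camera adjusted p was 5.0e-08, and the adjusted p = 0.10 with an estimated correlation. Among genes of NADPH supply 4 of 6 fell (4 adjusted over the list alone; camera adjusted p = 0.0043, adjusted p = 0.31 with an estimated correlation). They included Pgd, a pentose phosphate enzyme, which fell 2.90-fold, and Me1, malic enzyme, which fell 93.4-fold.

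Of the NRF2 pathway regulators 6 of 10 fell and 0 rose (6 adjusted over the list alone; camera adjusted p = 0.00075, adjusted p = 0.24 with an estimated correlation). Osgin1 fell 4.25-fold and Sqstm1, the autophagy receptor p62, fell 2.02-fold. The heme and iron list did not pass camera (adjusted p = 0.072), but it passed under 13 of 26 alternatives, among them limma on log2(FPKM + 1) at 0.024 and edgeR without WT replicate 3 at 0.016, over a range from 3.0e-05 to 0.16. In that list 3 of 7 fell and 1 rose (5 and 1 adjusted over the list alone). Blvrb and Hmox1, which break down heme and its products, fell 4.09-fold and 1.83-fold, and Blvra rose 1.91-fold. Over the 5 NRF2 lists 40 of 57 tested members fell, 2 rose and 15 did not pass.

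Matrix and contractile genes showed far larger differences. All 19 tested members of the collagen and crosslinking list fell (19 adjusted over the list alone), with a median of -6.89 and a camera adjusted p of 3.4e-13 (adjusted p = 0.31 with an estimated correlation). Fn1, fibronectin, fell from 5537 ± 2779 to 245 ± 13.4 CPM, and Tnc, tenascin C, fell 190-fold. The list summed to 5730, 14370 and 21660 CPM in WT replicates 1, 2 and 3, and to 305, 337 and 327 CPM in the knockout libraries. In the smooth muscle list 14 of 15 fell (14 adjusted over the list alone; median -7.33; camera adjusted p = 2.6e-08, adjusted p = 0.31 with an estimated correlation). Over the alternatives its median ran from -7.99 to -3.23, and that of the collagen and crosslinking list from -7.56 to -3.25. Tagln, an actin-binding protein of contractile cells, fell 204-fold. Myh11, smooth muscle myosin, had 1246 counts in WT and 2 in knockout, a count ratio of 631 (95% counting interval 174 to 5217) and an edgeR fold of 503.5.

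Genes that mark stromal cells fell with them. In the stromal stem cell and niche factor list 16 of 21 fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -4.68. Its camera adjusted p was 2.1e-06, with an adjusted p = 0.43 with an estimated correlation. Its median ran from -5.68 to -0.70 over the alternatives. It was -1.47 with limma on log2(FPKM + 1), with 7 of 14 lower, and -0.87 with edgeR at a mean FPKM of at least 5, with 4 of 8 lower, where camera did not pass (adjusted p = 0.091). Pdgfrb, a growth factor receptor, fell 60.5-fold and Csf1, the macrophage growth factor, fell 104-fold. All 9 tested Hox genes fell (9 adjusted over the list alone; median -5.39, or -5.26 with genes at 0 set to their bound; camera adjusted p = 3.2e-05, adjusted p = 0.40 with an estimated correlation). Hoxc10 had 609 counts in WT and 6 in knockout. The 9 genes were at low levels, summing to 11.34 CPM in WT replicate 1, and 1 of them was tested with limma on log2(FPKM + 1).

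In the osteoblast list 8 of 12 fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.040, adjusted p = 0.31 with an estimated correlation). Col1a1 fell from 2639 ± 1781 to 20.5 ± 9.94 CPM and Sparc fell 113-fold, while Bmp2 rose 4.73-fold. The summed RNA of the list did not fall, at 35640 ± 5404 CPM in WT and 38900 ± 1811 CPM in knockout. That sum was mostly Spp1, the most abundant gene in each of the 6 libraries, so it says little about the other members. Spp1 held 3.73% of counts in WT replicate 1, 2.14% in WT replicate 3 and 4.01% in knockout replicate 1. The whole osteoblast list, after TMM scaling, held 4.12%, 3.04% and 4.09% there. That list lost its call under 14 of 26 alternatives. Its adjusted p was 0.55 with limma on log2(FPKM + 1), where its median was -0.08, 0.086 without WT replicate 1, 0.054 without knockout replicate 2 and 0.39 when scaled to the macrophage list, over a range from 0.00059 to 0.84. All 3 tested chondrocyte genes fell (3 adjusted over the list alone; camera adjusted p = 0.0048, adjusted p = 0.24 with an estimated correlation), Col11a1 by 131-fold. In the adipocyte list, which did not pass camera (adjusted p = 0.90 as higher, against a median of -0.04), 2 of 12 rose and 3 fell (2 and 4 adjusted over the list alone). Pparg and Fabp4, expressed in fat cells and in macrophages, rose 5.27-fold and 3.33-fold, and Scd1 fell 38.2-fold.

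Of matrix proteases and inhibitors 12 of 15 fell and 1 rose (13 and 2 adjusted over the list alone; camera adjusted p = 4.6e-05, adjusted p = 0.25 with an estimated correlation), with Mmp2 down 73.2-fold and Timp1 down 47.2-fold. Wnt genes fell in 12 of 15 cases and rose in 1 (12 and 1 adjusted over the list alone; median -3.97, or -3.48 with genes at 0 set to their bound; camera adjusted p = 1.3e-05, adjusted p = 0.31 with an estimated correlation). Wnt5a, a secreted ligand, fell 168-fold. At a mean FPKM of at least 5 the Wnt median was -0.46, with 3 of 4 lower, the BMP and TGF-beta median was -1.49, with 5 of 9 lower, and the protease median was -1.14, with 6 of 8 lower. BMP and TGF-beta genes fell in 11 of 16 cases and rose in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 3.2e-05, adjusted p = 0.24 with an estimated correlation), Inhba by 100.1-fold. Notch genes fell in 5 of 7 cases (5 adjusted over the list alone; camera adjusted p = 0.0025, adjusted p = 0.24 with an estimated correlation), Jag1 by 2.19-fold.

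**Figure D2:**
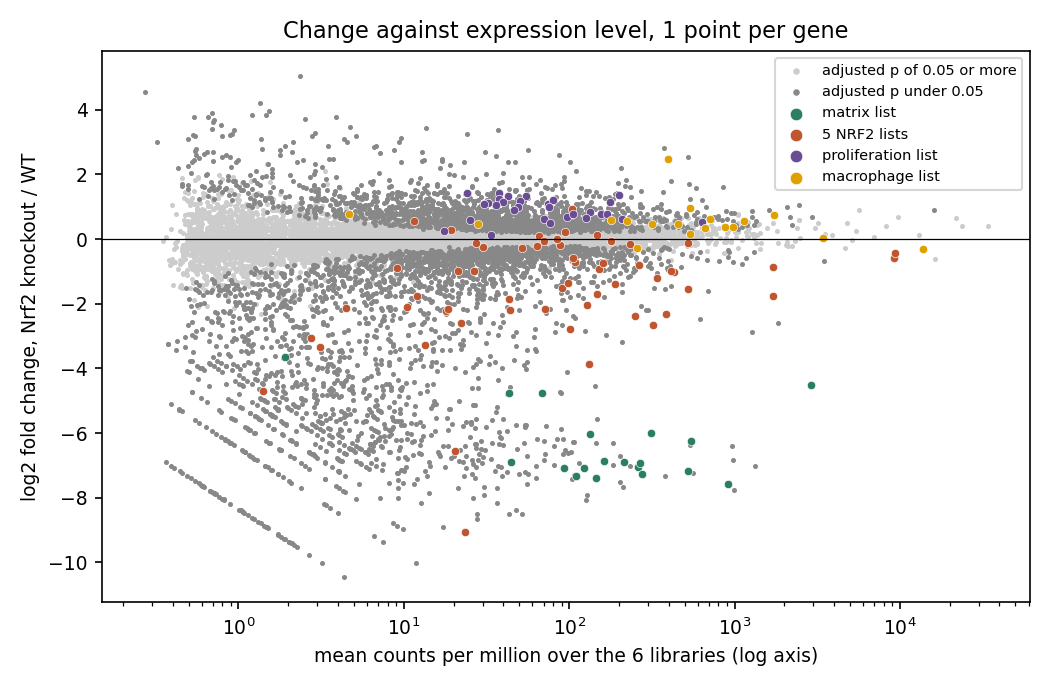
Log2 fold change of each tested gene (knockout over WT) against its mean CPM over the 6 libraries (log axis), with 4 sets of list genes in colour. The 19 matrix genes lie far below 0, and 40 of the 57 NRF2 list genes passed the test as lower.

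Macrophage genes were at like or higher levels in knockout. In the macrophage and monocyte list 5 of 18 rose, 0 fell and 13 did not pass (5 and 0 adjusted over the list alone), with a median of 0.47. Mrc1, the mannose receptor, rose 5.60-fold, from 120 ± 5.38 to 670 ± 42.4 CPM, and Cd14 rose 1.52-fold. The camera adjusted p was 0.00043, with an adjusted p = 0.50 with an estimated correlation. With the matrix covariate the median was -0.12 and the camera adjusted p 0.51. That covariate separates the genotypes, so results with it, here and below, extrapolate from the WT libraries and do not show matrix content removed. In the neutrophil and mast list 7 of 11 rose and 1 fell (7 and 1 adjusted over the list alone; median 2.37; camera adjusted p = 0.0051, adjusted p = 0.50 with an estimated correlation). The number called higher was 2 when scaled to the macrophage list (median 1.71) and 9 with the matrix covariate (median 3.88). The neutrophil granule genes Ngp and Elane rose 6.70-fold and 9.17-fold, and Mcpt8, a basophil protease, fell 108-fold.

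Markers of other cell types did not pass camera, though osteoclast genes passed with the matrix covariate (adjusted p = 0.0033) and endothelial genes when scaled to the macrophage list (adjusted p = 0.011). In the osteoclast list 1 of 7 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.90 as higher, against a median of -0.08), with Atp6v0d2, a proton pump subunit, up 3.44-fold and Ocstamp, a cell fusion gene, down 8.31-fold. Endothelial genes rose in 2 and fell in 1 of 6 cases (2 and 1 adjusted over the list alone; adjusted p = 0.29). Lymphocyte genes rose in 1 and fell in 1 of 3 (2 and 1 adjusted over the list alone; adjusted p = 0.58; median 0.86 but mean -0.56), erythroid and megakaryocyte genes fell in 2 of 3 (2 adjusted over the list alone; adjusted p = 0.29), and skeletal muscle genes rose in 1 and fell in 2 of 4 (1 and 2 adjusted over the list alone; adjusted p = 0.52). Of the sex-linked genes 1 of 4 fell (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.87).

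Proliferation genes were higher in knockout: 26 of 30 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 0.98. Birc5, which acts in cell division, rose 2.52-fold, and the replication helicase genes Mcm5 and Mcm3 rose 1.78-fold and 1.72-fold. The camera adjusted p was 1.0e-11, with an adjusted p = 0.31 with an estimated correlation. When libraries were scaled to the macrophage list, 0 of the 30 passed edgeR (4 had an unadjusted p under 0.05). The median there was 0.40, against -0.515 for all tested genes. With the matrix covariate 28 passed, but that covariate separates the genotypes, so this count does not show that matrix content was accounted for. In the p53 and arrest list 13 of 22 fell and 5 rose (14 and 6 adjusted over the list alone; camera adjusted p = 0.076, or 0.026 without WT replicate 1), with Cdkn2b down 28.5-fold and Cdkn2c up 2.86-fold. With the matrix covariate 5 fell and 4 rose, with a median of 0.03 and a camera adjusted p of 0.835 as higher. When scaled to the macrophage list the camera adjusted p was 0.837.

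Interferon-stimulated genes rose in 16 of 22 cases and fell in 0 (17 and 0 adjusted over the list alone), with a median of 1.01. Oasl1 and Oas2, antiviral genes, rose 7.37-fold and 5.62-fold. The camera adjusted p was 3.9e-07, with an adjusted p = 0.31 with an estimated correlation. The number called was 8 when scaled to the macrophage list (median 0.49, against -0.515 for all genes) and 6 with the matrix covariate (median 0.96). In the inflammatory and secretory list 8 of 18 rose and 6 fell (9 and 6 adjusted over the list alone). Its median was 0.72 and its mean -0.66, and camera, which read it as higher, did not pass it (adjusted p = 0.29, or 0.00041 when scaled to the macrophage list). Ccl2, a monocyte chemokine, rose from 73.2 ± 12.3 to 337 ± 19.8 CPM, and Igfbp5, a growth factor binding protein, fell 34.9-fold.

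Genes of glycolysis and hypoxia fell in 15 of 23 cases and rose in 1 (16 and 1 adjusted over the list alone; median -0.66; camera adjusted p = 5.3e-06, adjusted p = 0.31 with an estimated correlation). Bnip3 fell 2.74-fold, Vegfa fell 2.19-fold and Slc2a1, a glucose transporter, fell 1.95-fold. Immediate-early genes fell in 7 of 13 cases and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.25 with an estimated correlation), Ier3 by 8.08-fold. Heat shock genes fell in 5 of 11 cases (5 adjusted over the list alone; camera adjusted p = 0.020, adjusted p = 0.50 with an estimated correlation), Hspb1 by 103-fold. With the matrix covariate the heat shock call ended (adjusted p = 0.84), with a median of -0.04 and 2 lower and 1 higher. Nuclear-encoded oxidative phosphorylation genes passed camera as higher (adjusted p = 0.010, adjusted p = 0.61 with an estimated correlation). The call was lost under 11 of 26 alternatives, among them limma on log2(FPKM + 1) at 0.061 and edgeR without knockout replicate 2 at 0.071, over a range from 0.00064 to 0.73. In that list 1 of 28 passed alone, Cox5a at 1.24-fold (0 adjusted over the list alone), and the median was 0.13. When scaled to the macrophage list it was -0.37, where the median of all tested genes was -0.515.

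The remaining lists did not pass camera, and their counts adjusted over the list alone follow in brackets. Members called higher and lower were 3 and 7 of 21 for ATF4 and unfolded protein response (3 and 9; adjusted p = 0.33) and 1 and 2 of 19 for autophagy and lysosome (0 and 1; adjusted p = 0.26, or 0.026 as higher without WT replicate 1 and 0.010 as lower with the matrix covariate). They were 3 and 1 of 25 for the proteasome (1 and 1; adjusted p = 0.26), 0 and 2 of 19 for cholesterol synthesis (0 and 2; adjusted p = 0.87; median 0.07, mean -0.24) and 3 and 3 of 15 for fatty acid metabolism (3 and 3; adjusted p = 0.90 as higher, median -0.05). None of the 10 mitochondrially encoded genes was called by edgeR (adjusted p = 0.52 for the list). Genes near Nfe2l2 had 1 higher and 5 lower of 21 (1 and 5; adjusted p = 0.90; median 0.06, mean -0.50). Of 4 strain-variable genes 2 rose (2; adjusted p = 0.18), Wdfy1 by 1.83-fold and Cyfip2 by 1.96-fold. Of the 40 lists, 22 passed camera with the preset correlation, 5 as higher and 17 as lower, and 0 passed with an estimated correlation.

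**Figure D3:**
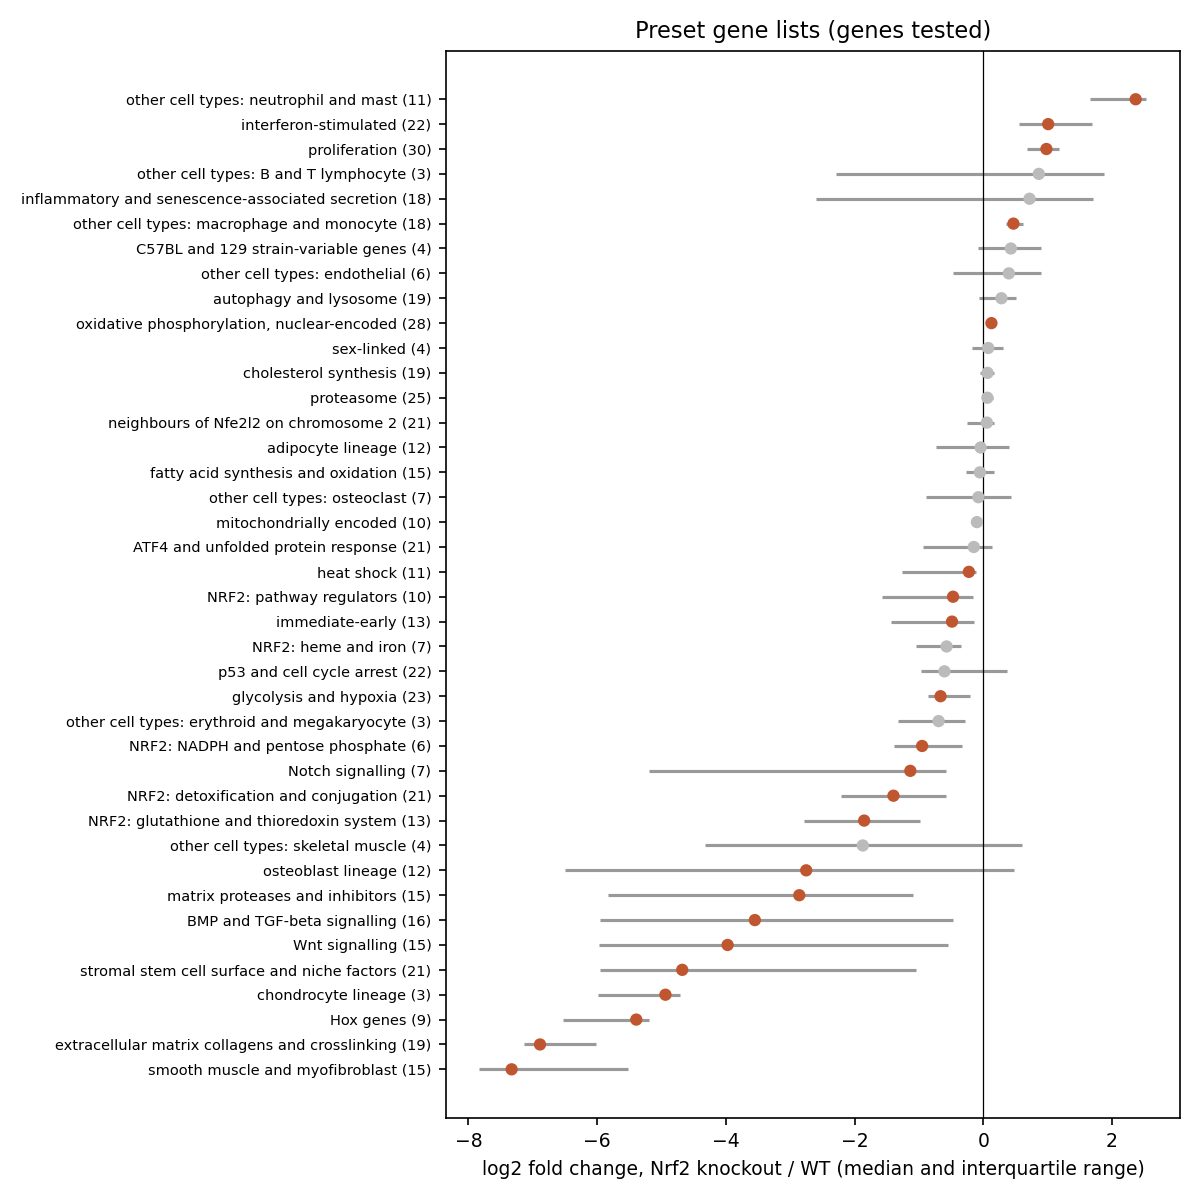
Median log2 fold change (points) and interquartile range (lines) of the 40 gene lists, knockout over WT, with the number of genes tested in brackets and lists with a camera adjusted p under 0.05 in orange. The smooth muscle list lies lowest at -7.33 and the neutrophil and mast list highest at 2.37.

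Among single genes, the largest increases included Ccl8, a chemokine, at 13.1-fold. Cyp2s1, a cytochrome P450, rose 10.3-fold, from 6.55 ± 0.97 to 67.4 ± 3.08 CPM (edgeR adjusted p = 4.0e-05). Ifi27l2a, Cbr2, Ccl12, Ifitm6 and Dppa3 rose between 7.19-fold and 9.54-fold. Il1rn, the interleukin 1 receptor antagonist, rose 7.03-fold to 653 ± 29.0 CPM. The largest decreases included Nbl1, with 1080 counts in WT and 2 in knockout, a count ratio of 547 (95% counting interval 151 to 4523) and an edgeR fold of 439.6. Gzmc, a granzyme, had 505 counts in WT and 1 in knockout, a count ratio of 512 (91.4 to 20250) and an edgeR fold of 351.9. By edgeR, Ankrd1, Cnn1, Prss23, Gzmd, Ccn4 and Adam12 fell between 289-fold and 482-fold. Among them Gzmd, Ankrd1 and Prss23 had 4, 8 and 9 knockout counts. The 95% counting intervals of their count ratios were 217.5 to 2048, 226.7 to 1037 and 208.2 to 865.9.

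Of 1203 annotation terms, 15 were enriched among higher genes and 153 among lower genes at a Benjamini-Hochberg adjusted p under 0.05 in one-sided Fisher exact tests. Cell division had 98 of 264 genes higher, where 39.4 were expected (adjusted p = 2.2e-16), and defense response to virus had 29 of 75 (adjusted p = 6.1e-05). Extracellular matrix organization had 39 of 55 genes lower, where 11.1 were expected (adjusted p = 7.6e-13), and cell adhesion had 75 of 165 (adjusted p = 1.0e-10).

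WT libraries varied much more than knockout libraries. The biological coefficient of variation was 25.2% in WT and 6.5% in knockout. Pearson correlations across genes, which are not independent replicates, were 0.952 to 0.987 within WT, 0.991 to 0.993 within knockout and 0.807 to 0.926 between genotypes. The first principal component held 90.6% of the variance and separated the genotypes, with WT at -39.7, -88.1 and -109.2. Genes lower in knockout were mostly ordered in WT as the matrix list was: 1810 of 2468 (73.3%), and 824 of the 890 lower by at least 8-fold (92.6%), were lowest in WT replicate 1 and highest in WT replicate 3, against 27.0% of genes not called.

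**Figure D4:**
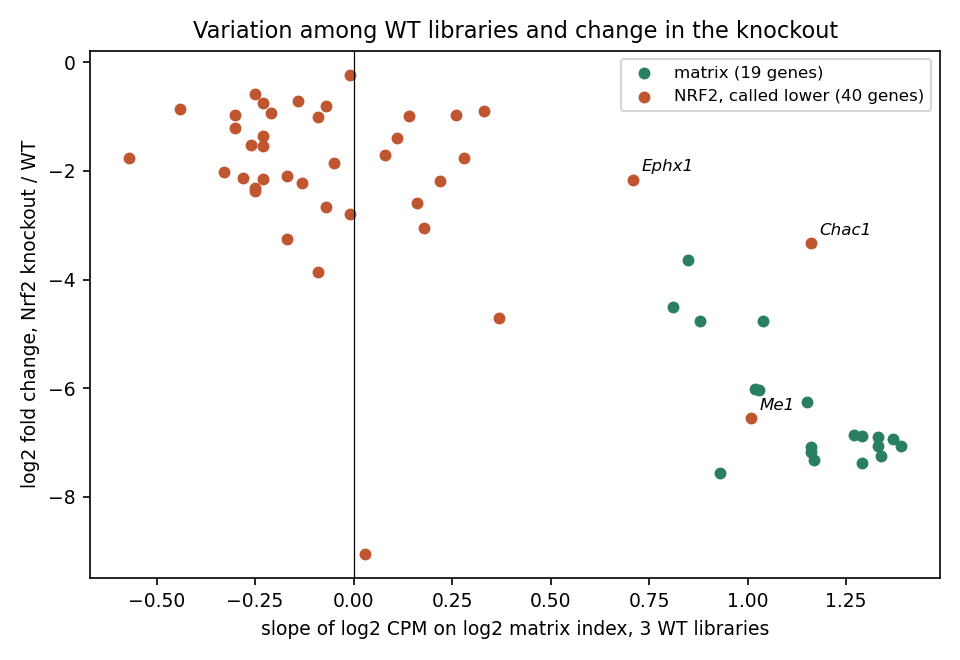
Log2 fold change (knockout over WT) against the slope of log2 CPM on the log2 matrix index over the 3 WT libraries, for 19 matrix genes and 40 NRF2 list genes called lower. The matrix genes have a median slope of 1.16 and the NRF2 genes a median slope of -0.09, with Ephx1, Me1 and Chac1 to the right.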

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

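Of 175 named genes other than Nfe2l2, 120 kept direction and side of the threshold under every alternative that tested them. Alternatives with other filters did not test all 175, and a gene left untested there was not counted as moved. Nfe2l2 was called lower in all alternatives, with a log2 fold change from -5.26 to -2.94. The cause of the shifts below was not tested except where named. Leaving out 1 library gave 2491 to 6901 changed genes, 875 to 3188 higher, 1616 to 3713 lower, 1722 to 2800 changed at least 2-fold, 20 to 23 lists and 9 to 19 higher terms. With limma on log2(FPKM + 1) 1431 genes were lower, 797 changed at least 2-fold and 86 terms were lower. The same 3 counts were 1463, 1072 and 85 with a pseudocount of 0.1, and 1343, 393 and 82 with 5, where a larger pseudocount shrinks folds by construction. They were 1374, 843 and 81 after quantile normalization, 1322, 838 and 74 after median centring, and 1600, 801 and 70 after TMM on FPKM. They were 1403, 791 and 80 with ordinary eBayes and 1417, 782 and 82 with robust eBayes. Array weights gave 7803 changed genes, 3583 higher and 4220 lower, with 827 changed at least 2-fold and 36 lower terms. A mean FPKM of at least 5, which tests fewer genes, gave 2019 changed, 982 higher, 1037 lower, 513 at least 2-fold, and 6 higher and 20 lower terms. No filter gave 28 higher terms. An adjusted p under 0.01 left 2123 changed genes, 734 higher and 1389 lower. With an estimated correlation 0 lists passed camera, against 22 with the preset one and 26 with fry. Of the 22 lists past camera, alternatives ended the call most often for the osteoblast list (14 of 26) and oxidative phosphorylation (11 of 26). A single alternative ended it for the stromal stem cell list (0.0905) and the immediate-early list (0.106), both at a mean FPKM of at least 5, for Notch (0.117, array weights), and for heat shock (0.835) and macrophage genes (0.506), both with the matrix covariate. Lists that gained a call were heme and iron (13 of 26), p53 (3 of 26, lowest 0.0145), mitochondrially encoded genes (0.0303, quantile normalization) and autophagy, as higher without WT replicate 1 and as lower with the matrix covariate (0.0101). With that covariate adipocyte (0.0209) and cholesterol genes (0.000585) gained a call as lower, where camera had read them as higher, and osteoclast (0.00331) and strain-variable genes (0.0269) gained one as higher, and with scaling to the macrophage list inflammatory (0.000414) and endothelial genes (0.0111) and strain-variable genes did. Chosen after seeing the data, scaling to the macrophage list left 303 higher genes, and the matrix covariate left 2614 changed and 948 higher genes and gave 29 higher terms. DESeq2 called 4638 genes and the upper quartile fit 4210. Reversals were seen only for genes not called under that alternative. Scaling to the macrophage list turned Cox5a (-0.19), Uqcrfs1 (-0.27), Uqcrc2 (-0.31), Sdha (-0.32), mt-Co3 (-0.18), Psma1 (-0.24), Psmd12 (-0.30), Srebf2 (-0.25), Ctsk (-0.03), Pf4 (-0.34), Mylpf (-0.10), Kdm5d (-0.15) and Uty (-0.22). The covariate turned Npc2 (-0.02), Srebf2 (-0.03), Gm4737 (0.50), Itgb3 (0.17), Pf4 (-0.23), Mylpf (-0.50) and Ddx3y (0.24). Gm4737 was at 0.02 after quantile normalization and 0.05 after median centring, and ran from -0.15 to 0.13 when 1 library was left out, with 0.13 without WT replicate 3 and 0.07 without knockout replicate 2. Keap1 was at 0.01 after median centring and Ddx3y ran from -0.20 to 0.02 when 1 library was left out, with 0.02 without WT replicate 3. With the replicate number as a replicate block 4174 genes changed, 1811 higher and 2363 lower, and 22 lists passed. Deviations of same-numbered libraries correlated at 0.203, 0.136 and 0.078. Those of differently numbered libraries ran from -0.166 to 0.085, the highest for WT replicate 3 with knockout replicate 2. Whether the numbers pair the libraries stays open. Depth limits the genes lower by the largest factors, whose knockout counts were in some cases under 10.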

Other observations

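The gene families in the next paragraph and the tests of the matrix, NRF2, proliferation and Nfe2l2 neighbour patterns were chosen after the results were seen. The splits of the libraries were planned.

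Genes were grouped by the letters that open their symbol, and 418 tests of families with at least 8 tested genes were run, by direction. Of 10 tested Ccl chemokine genes 8 rose (1.42 expected; one-sided Fisher exact test, adjusted p = 0.00057), and 8 were called higher under each of 4 other scalings. Ccl6 rose 5.76-fold to 895 ± 101 CPM and Ccl9 rose 3.27-fold to 812 ± 34.7 CPM. All 10 tested Adamts proteases, which cut matrix proteins, fell (1.87 expected; adjusted p = 1.1e-05), Adamts12 by 140-fold. Of 12 tested semaphorin genes 8 fell and 1 rose (adjusted p = 0.019), and of 9 sulfotransferase genes of the Chst family 7 fell and 1 rose (adjusted p = 0.012). Of 10 Mcm genes 8 rose (adjusted p = 0.00057), but 0 were called when scaled to the macrophage list. The families named here are a selection of those that passed. Of 23 Col genes 18 fell and 1 rose (adjusted p = 4.0e-07). Of 31 Kif genes 14 rose and 6 fell (adjusted p = 0.0025 for the rise), but 0 were higher and 8 lower when scaled to the macrophage list.

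Matrix, contractile and stromal genes were lower in knockout by the largest factors. An unchanged number of stromal cells with a lowered matrix and contractile programme is argued against by Hox genes and the stromal factors Foxc1, Ebf1, Ebf3 and Prrx1. Their median log2 fold change was -5.55 over 13 genes (75th percentile -5.26), although stromal cells that lost these factors as well are not excluded. The Hox genes among them were at low levels, summing to 37.55 CPM in WT and 0.99 CPM in knockout. Fewer stromal cells in knockout cultures may account for the pattern: 96.7% of the 30 smooth muscle and stromal list members called lower followed the matrix index over WT libraries, against 27.0% of genes not called. These members vary together over the same 3 libraries, so they are not 30 independent observations. A matrix and contractile programme that varied between WT cultures would give the same order, so the percentage does not tell cell number and programme apart. Whether loss of Nrf2 or the make-up of the individual cultures set the number of stromal cells stays open. The origin of the cultures is not given in the sources used here.

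NRF2 target genes were also lower, and 1 explanation is argued against, for the 40 members called lower as a set. Loss of stromal cells that carried these transcripts would give slopes near those of matrix genes among WT libraries, yet the 40 members called lower had a median slope of -0.09 (75th percentile 0.15) against 1.16 for the matrix list, which lies near 1 by construction. Chac1, Me1 and Ephx1 are exceptions, with slopes over half-way to the matrix median, and for them this explanation stays open. The slopes rest on 3 libraries over which genes vary together, so the percentile is a spread over genes and not an error bound. Genes that vary widely among WT libraries are less readily called, which favours slopes near 0, and the 15 members that did not pass were left out. Scaling moves all genes about alike, so it cannot bear on the fall relative to all genes. There the 57 members tested had a median that differed from that of all genes by -1.01 (75th percentile -0.22). The fall in absolute terms stays open, since the 4 other scalings moved all genes up by 0.005 at most. Under these scalings at least 39 of the 40 were still called. A fall relative to other genes through loss of NRF2 within the cells is a candidate explanation, as a hypothesis found and tested on the same data.

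Proliferation genes were higher, and whether a higher share of macrophages in knockout libraries accounts for the rise stays open. That share would need members to follow the macrophage list among WT libraries with a slope near 2.09. The macrophage list's own median slope was 1.19. The members' median slope was -1.01 (75th percentile -0.43), and Pcna alone was above 1.05. Over the 3 WT libraries the macrophage list fell as the matrix index rose, so slopes on the 2 cannot be told apart. The members also vary together over these libraries, so they are not independent observations. A scaling moves all genes about alike, so it cannot bear on the rise relative to all genes. There the list's median lay 0.99 above that of all genes (25th percentile 0.68), though with an estimated correlation camera did not pass the list (adjusted p = 0.31). Whether the list rose in absolute terms stays open with the choice of scaling: scaled to the macrophage list, the median went from 0.98 (median SE 0.19) to 0.40 (median SE 0.31), and the calls from 26 to 0, as the fold shrank and the spread grew. A direct effect of Nrf2 on cell division was not tested.

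There are 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05. For each of the following results 1 of the 10 splits, the real one, gave a count as large. The real split gave 4333 changed genes, 2063 changed at least 2-fold, 22 lists and 168 terms, and the highest of the other splits gave 0, 0, 16 and 0.

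A strain segment carried along with the targeted allele could raise calls near Nfe2l2. Within 10 Mb of it 35 of 89 tested genes were called (39.3%), against 32.8% elsewhere. The odds ratio was 1.33 (95% interval 0.84 to 2.07; Fisher exact p = 0.213, two-sided), so these counts do not decide it.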
